A study of Mus musculus with 26 samples.

How the data were processed

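RNA was measured in the aorta and the mesenteric arteries of male mice, 26 libraries in all and 13 per tissue (WT sham n = 4, WT AngII n = 4, KO AngII n = 5). Per the labels' protocols, RNA was purified with the PureLink RNA Micro kit, poly(A) libraries were made with the NEBNext Ultra II Directional kit, and 2 × 150 bp reads were obtained on an Illumina NovaSeq. The deposited values are read counts per Ensembl gene, 1 table per library, and per the submitters' processing notes they come from cutadapt, HISAT2 and HTSeq on the mouse build GRCm39. Versions, settings, the annotation release and the strand setting of the counting are not given in those notes. The aortic tables list 55416 gene identifiers and those of the mesenteric arteries 55414 of the same; symbols were taken from a reference table for 52083 and 52081 of them.

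The 5 summary lines of each HTSeq table stayed out of library sizes and tests. As shares of all records they were 6.635 to 11.12% without a feature, 1.17 to 1.613% ambiguous, 1.96 to 3.555% of low alignment quality, 0.5717 to 14.7% not aligned and 4.816 to 12.99% aligned to several places. Counts assigned to genes came to 23.49 to 32.25 M per aortic library and 17.54 to 30.05 M per mesenteric library. No table was a copy or a resequencing of another of its group and tissue, the pairs compared: over the 22 pairs of libraries of the same group in each tissue, the chi-square per degree of freedom between counts was 9.086 to 172.8 in the aorta and 19.6 to 254.8 in the mesenteric arteries.

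Each tissue was fitted apart, with its 3 groups in 1 model, by edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and groups were compared by the robust quasi-likelihood F test. A gene is called when its Benjamini-Hochberg adjusted p is below 0.05, and a rise or fall is stated only for called genes or lists. Values after ± are standard errors for log2 fold changes and SD for CPM, and intervals are 95% intervals. Log2 CPM values carry a prior count of 2. The difference between tissues was tested as an interaction in a fit of all 26 libraries over the identifiers that the tables of the 2 tissues share. Exact two-sided permutation tests regrouped the libraries of the 2 groups compared in every way.

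Gene lists were written from general knowledge before the data were examined. Their 854 distinct symbols all matched an identifier, though some symbols shared an identifier. There were 46 lists, 14 of cell type markers and 32 of biological groups. They were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, then with the correlation estimated from the residuals, and with fry as a self-contained test. Adjustment was over the 46 lists of a comparison. Members were counted with p adjusted over all genes and again with p adjusted over the list alone.

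The rule for naming genes was fixed in advance. It takes Sphk1, the 8 largest increases and 8 largest decreases of each main comparison among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, and from each list up to 4 called members with the smallest adjusted p, or up to 2 members as values only where none was called. For tissue differences it takes 5 genes per direction by adjusted p. Predicted genes without a name were counted and not named. The text uses a selection of the genes that the rule takes, made with their values in view. Further genes in small counts, and genes called only under an alternative, were named after their values were seen.

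The opposition of the AngII and KO effects was set against 20 simulations of unchanged groups that share the WT AngII libraries, against 20 with an AngII effect and no KO effect, and against 6 splits of those libraries 2 and 2. Alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a stricter filter, fits of only the 2 groups compared, limma voom with sample quality weights, the replicate number as a block, the adipocyte marker level as a covariate, and each library left out. Those chosen after seeing the data concern the mesenteric arteries only: leaving out KO replicate 3 and WT AngII replicate 1, leaving out the 4 libraries with over 10% of records not aligned, and covariates for lymphoid and for gut and pancreas markers.

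The methods were tested on simulated data, with counts drawn from the real means and library sizes and 200 genes changed by known folds. The changed genes were taken from those with an average log2 CPM of at least 1. Each gene was drawn independently of the others. After AngII, edgeR recovered 62.7% of the genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold in the aorta (16635 genes), and 28.4%, 62.7% and 89.4% in the mesenteric arteries (17320 genes). For the tissue difference of the AngII effect it recovered 14.9%, 67.2% and 87.9% (18180 genes), and for that of the KO effect 25.4%, 50.7% and 84.8% (18196 genes). Camera at its preset correlation called 2 of 2 changed lists, made up only of genes changed in 1 direction, and 0 of 38 unchanged lists in each tissue. Since the simulated genes varied independently, this cannot show how often that setting calls unchanged lists whose genes vary together.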

Results

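Poly(A) RNA was sequenced from the aorta, a large elastic artery, and from the mesenteric arteries, the small muscular vessels that supply the gut, of male mice. The mice carried loxP-flanked alleles of Sphk1 on a C57BL/6J background. Sphk1 encodes sphingosine kinase 1, an enzyme that phosphorylates sphingosine to sphingosine-1-phosphate, a lipid that signals through the S1pr receptors. Mice without Cre are called wild type (WT) here. Mice with Cre driven by the promoter of the smooth muscle gene Tagln are called knockout (KO). Hypertension was induced at 12 to 14 weeks of age by a 14-day infusion of angiotensin II (AngII), a vasoconstrictor peptide, at 490 ng/kg/min from an implanted pump. Each tissue had 13 libraries: 4 of WT sham mice, 4 of WT mice given AngII and 5 of KO mice given AngII. No sham KO group was analysed here, so the deletion was compared only under infusion. The libraries held 23.49 to 32.25 M counts assigned to genes in the aorta and 17.54 to 30.05 M in the mesenteric arteries. The spread between replicates was larger in the mesenteric arteries, with a common dispersion of 0.127 against 0.0286 in the aorta.

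The targeted gene was examined in every library before any other. In the aorta, Sphk1 (ENSMUSG00000061878) stood at 4.31, 5.08, 6.03 and 3.04 normalised CPM in the sham libraries, at 24.2, 22.9, 16.1 and 11.55 CPM in the WT AngII libraries and at 2.64, 1.85, 1.715, 3.29 and 3.03 CPM in the KO libraries. AngII raised Sphk1 by 2.02 ± 0.27 on the log2 scale (SE; 18.7 ± 5.94 against 4.62 ± 1.26 CPM, mean ± SD, n = 4 each; edgeR adjusted p = 0.000136). In KO aortas Sphk1 fell by 2.90 ± 0.262 from the WT AngII level to 2.51 ± 0.701 CPM (n = 5), 13.4% of that level (edgeR adjusted p = 0.00046). The exact two-sided permutation p was 0.00794, the smallest that the 126 regroupings allow. In the mesenteric arteries the sham libraries held 8.58 ± 0.994 CPM and the WT AngII libraries 13.9 ± 3.28 CPM (n = 4 each). The log2 difference of 0.70 ± 0.204 did not pass edgeR's adjustment over all genes (adjusted p = 0.241; exact permutation p = 0.0286 for this gene taken alone). KO mesenteric arteries held 3.92 ± 0.904 CPM (n = 5), which fell by 1.83 ± 0.195 from the WT AngII level (edgeR adjusted p = 0.0101; exact permutation p = 0.00794). All KO libraries lay below all WT AngII libraries of their tissue, so the genotype labels and the counts go together. The deletion is confined to cells that express Tagln, and the position of the floxed exons is not given in the sources used here.

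**Figure D1:**
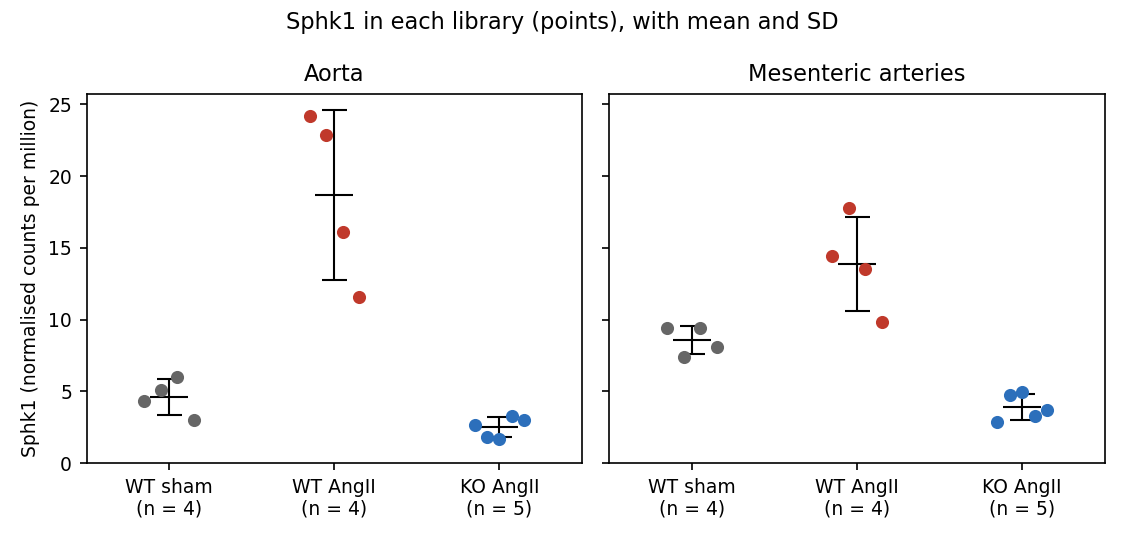
Sphk1 level in each library, in normalised CPM (vertical axis, linear from 0), by group in the aorta (left) and the mesenteric arteries (right); points are libraries, and the bars give the mean and SD of each group. The 4 aortic WT AngII libraries lie between 11.55 and 24.2 CPM and the 5 aortic KO libraries between 1.715 and 3.29 CPM.

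The effect of AngII in mice with intact Sphk1 was measured by comparing WT AngII with WT sham vessels. In the aorta, the largest increase among called genes with a mean log2 CPM of at least 1 was that of Col11a1. This minor fibrillar collagen of cartilage rose by 7.83 ± 1.49 on the log2 scale (SE), from 0.243 ± 0.122 to 55.4 ± 62.9 CPM (mean ± SD, n = 4 each; edgeR adjusted p = 0.00306). Chad, the cartilage protein chondroadherin, rose by 5.67 ± 1.06, and Spp1 (osteopontin) rose by 5.53 ± 0.495. Cthrc1, a secreted collagen-associated protein of injured arteries, rose by 5.44 ± 0.692, and Tnmd (tenomodulin), a tendon protein, by 5.35 ± 1.02 (edgeR adjusted p between 2.43e-05 and 0.00316 for these 4 genes). Col8a1, a short-chain collagen, rose by 4.06 ± 0.495, Ddah1, which breaks down the nitric oxide synthase inhibitor dimethylarginine, by 4.15 ± 0.877, and Ttc9 by 3.93 ± 0.313. Among the 8 largest decreases, Adra2a, the alpha-2A adrenergic receptor, fell by 2.04 ± 0.308, and Kcnip4, a potassium channel subunit, by 2.00 ± 0.164. Mmp9, a gelatinase, fell by 1.87 ± 0.27, Slc16a11, a monocarboxylate transporter, by 1.86 ± 0.207, and Upb1, an enzyme of pyrimidine breakdown, by 1.84 ± 0.272. AI838599 fell by 1.96 ± 0.162. Lower counts were also found for Olfr224 (log2 fold change -2.15 ± 0.312) and the antisense gene Atcayos (-2.06 ± 0.291), which are uncertain. Olfr224 belongs to a large receptor family, and Atcayos is read from the strand opposite to another gene, with a strand setting of the counting that is not given.

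Matrix genes rose as groups in the WT aorta. Of 21 fibrillar and basement membrane collagen genes tested, 20 rose and 0 fell, and 21 rose when adjusted over the list alone. Col1a1, the main collagen of fibrous tissue, went from 1917 ± 229 to 10290 ± 3150 CPM (log2 fold change 2.42 ± 0.23), and Col5a2 rose by 1.80 ± 0.127. Of 20 matricellular and injury matrix genes, 17 rose (18 adjusted over the list alone), among them Sparc by 1.90 ± 0.146, Thbs1 (thrombospondin 1) by 3.02 ± 0.246 and Tnc (tenascin C) by 1.36 ± 0.113. All 21 genes of secretion and collagen maturation rose, including P4ha3, a prolyl hydroxylase subunit, by 3.91 ± 0.413 and Plod2, a lysyl hydroxylase, by 1.19 ± 0.13. Of 19 elastic fibre and crosslinking genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone). The lysyl oxidases Lox and Loxl2 rose by 1.82 ± 0.139 and 1.82 ± 0.155 and fibrillin Fbn1 by 1.25 ± 0.11. The 4 lists stood above the remaining genes in camera tests, with an adjusted p of 0.00513 for collagen, 0.00378 for matricellular, 0.0484 for maturation and 0.00513 for elastic fibre genes with an estimated correlation.

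Proteases and their inhibitors, cartilage and bone genes, growth factors and cell division genes also rose in the WT aorta. Of 23 matrix proteases and inhibitors, 13 rose and 2 fell (14 and 2 adjusted over the list alone). The inhibitor Timp1 rose by 2.42 ± 0.262, while Mmp9 fell, as given above. Of 16 osteochondrogenic genes, 11 rose and 1 fell with either adjustment, over all genes or adjusted over the list alone. Comp, a cartilage matrix protein, rose by 2.15 ± 0.29, Acan (aggrecan) by 1.78 ± 0.171 and Runx2, a transcription factor of bone, by 1.57 ± 0.238. Of 24 growth factor genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone), including Igf1 by 2.34 ± 0.301 and Pdgfc by 0.99 ± 0.0936. Of 30 cell cycle genes, 27 rose and 0 fell with either adjustment, including adjusted over the list alone. The topoisomerase Top2a rose by 2.70 ± 0.247, the proliferation marker Mki67 by 2.35 ± 0.248 and the mitotic kinase Cdk1 by 2.32 ± 0.219. With an estimated correlation, camera gave an adjusted p of 0.00378 for proteases and for growth factors, 0.00513 for osteochondrogenic genes and 0.046 for the cell cycle.

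Some other genes of sphingosine-1-phosphate handling were called in the WT aorta too. Of 14 tested, Sphk1 included, 7 rose and 1 fell (7 and 5 adjusted over the list alone). Spns2, the transporter that exports sphingosine-1-phosphate from cells, rose by 1.34 ± 0.178 and the receptor gene S1pr2 by 0.72 ± 0.118, and Plpp1, a lipid phosphate phosphatase, rose by 0.68 ± 0.114. The list was above the other genes with camera's preset correlation (adjusted p = 0.0317) and not with an estimated correlation (adjusted p = 0.133). Of 13 renin-angiotensin genes, 3 rose and 3 fell (6 and 3 adjusted over the list alone), with Ace, the angiotensin converting enzyme, up by 0.73 ± 0.102 and Rgs5, a regulator of G protein signalling, lower by a log2 fold change of -0.59 ± 0.14. The list as a whole was not called (camera adjusted p = 0.263, and adjusted p = 0.417 with an estimated correlation). Of 25 TGF-beta and BMP signalling genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone), among them the activin antagonist Fst up by 2.62 ± 0.238 and Tgfb3 by 0.82 ± 0.0992. That list was not called either (camera adjusted p = 0.223, and adjusted p = 0.47 with an estimated correlation).

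Genes of vascular tone fell more often than they rose in the WT aorta. Of 33 vasoconstrictor and vasodilator genes, 9 fell and 4 rose (10 and 4 adjusted over the list alone). Gucy1a1 and Gucy1b1, the subunits of the nitric oxide receptor guanylate cyclase, fell by 1.23 ± 0.127 and 1.04 ± 0.152, and Calcrl, the receptor for calcitonin gene-related peptide and adrenomedullin, by 1.05 ± 0.138. Of 30 ion channel and calcium handling genes, 11 fell and 3 rose (14 and 3 adjusted over the list alone). The potassium channel gene Kcnq5 fell by 1.00 ± 0.135, whereas the mechanosensitive channel gene Piezo1 rose by 0.76 ± 0.0906. Both lists were below the other genes with the preset correlation and not with an estimated correlation (adjusted p = 0.288 and 0.174). In the NADPH oxidase and antioxidant list 9 of 22 genes rose and 1 fell (10 and 2 adjusted over the list alone). Noxo1, the organiser of the Nox1 oxidase, fell by 1.31 ± 0.114, and Ncf1, its phagocyte counterpart, rose by 1.12 ± 0.144. That list was not called (camera adjusted p = 0.0899, and adjusted p = 0.188 with an estimated correlation).

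Markers of several cell types moved together with these groups. Of 12 macrophage and monocyte markers, 11 rose (11 up and 1 down adjusted over the list alone), with Ccr2, the monocyte chemokine receptor, up by 3.03 ± 0.423 and Cd68 by 1.00 ± 0.12. Of 12 fibroblast markers, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with Lum (lumican) up by 2.18 ± 0.394 and Dpt (dermatopontin) by 1.44 ± 0.256. Of 16 smooth muscle markers, 4 fell and 0 rose with either adjustment, including adjusted over the list alone, with Lmod1 (leiomodin 1) lower by a log2 fold change of -0.65 ± 0.158. Endothelial markers went both ways (2 up and 2 down of 12, and 2 and 4 adjusted over the list alone), with a median of -0.138, a mean of 0.0802 and a camera adjusted p of 0.639. The first 3 lists were called with the preset correlation and not with an estimated correlation (adjusted p = 0.139, 0.347 and 0.531). As the mean over each list, macrophage markers were 0.77 log2 units higher and fibroblast markers 0.57 higher after AngII (exact permutation p = 0.0286 for each, before adjustment for 14 lists). For smooth muscle markers the difference was -0.37 (exact permutation p = 0.114).

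In all, 2475 genes rose and 1826 fell of 16863 tested in the WT aorta (25.5%; edgeR quasi-likelihood test, adjusted p below 0.05), 908 and 364 of them by at least 2-fold. For 70.5% of genes the 95% interval of the AngII effect lay within a 2-fold change either way. The split between higher and lower calls depended on the scaling. With library size alone and no composition factor, 1747 genes rose and 3729 fell. That scaling put the median log2 fold change of all genes at -0.126. Col11a1, whose SD between WT AngII libraries exceeded its mean, lost its call with limma voom (adjusted p = 0.0757).

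**Figure D2:**
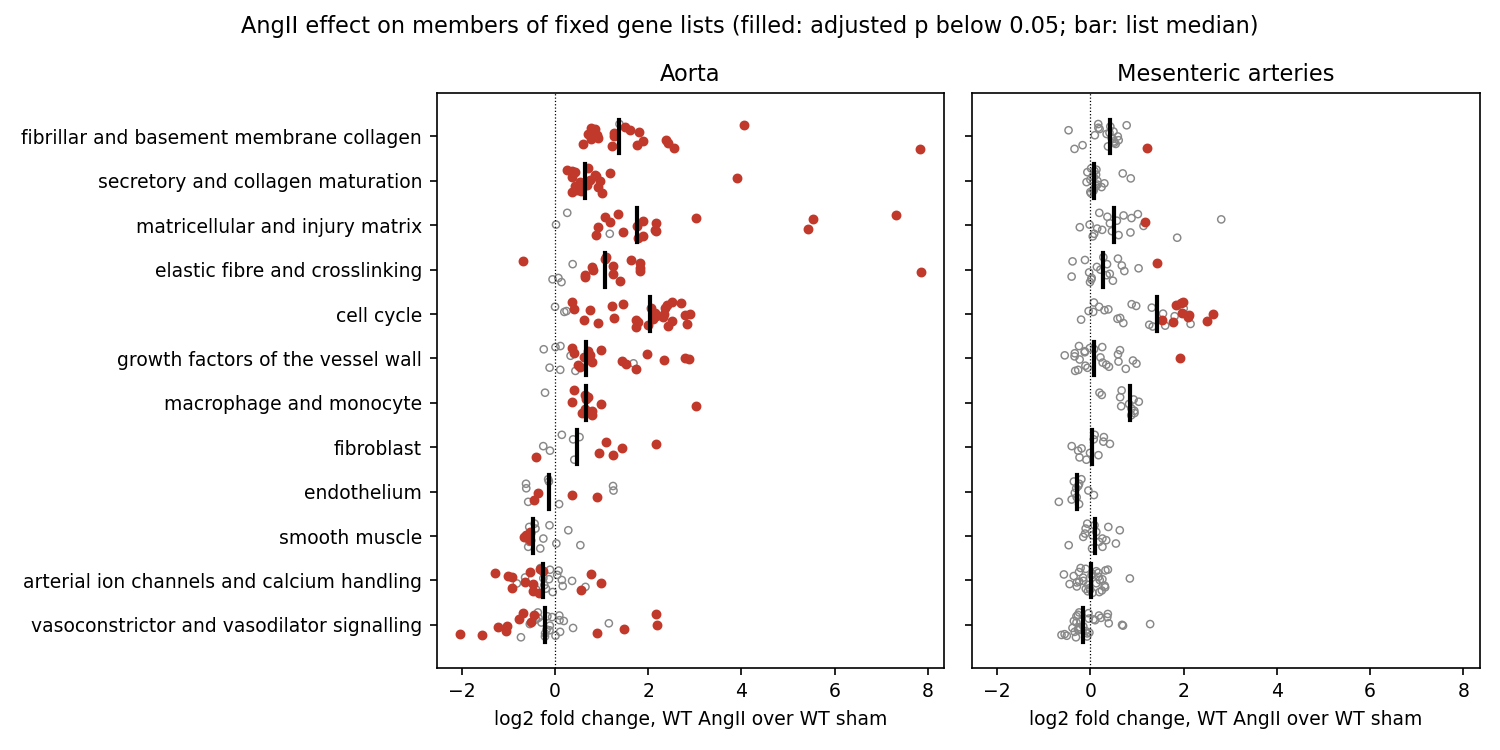
AngII effect (log2 fold change, WT AngII over WT sham, horizontal axis) on the members of 12 gene lists in the aorta (left) and mesenteric arteries (right); each point is a gene, filled where the edgeR adjusted p is below 0.05, and the black bar is the list median. In the aorta the cell cycle list has a median of 2.03 and the collagen list one of 1.38, against 1.43 and 0.43 in the mesenteric arteries.

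In WT mesenteric arteries, AngII raised a smaller set of genes led by cell division. Hmmr, a spindle-associated hyaluronan receptor, rose by 2.64 ± 0.354 on the log2 scale (SE), from 0.717 ± 0.342 to 4.47 ± 0.271 CPM (mean ± SD, n = 4 each; edgeR adjusted p = 0.0114). The mitotic genes Iqgap3 (2.51 ± 0.277), Ccnb1 (2.51 ± 0.381), Pbk (2.44 ± 0.283), Ckap2 (2.35 ± 0.325), Cenpf (2.13 ± 0.281), Cdk1 (2.09 ± 0.321) and Ckap2l (2.08 ± 0.255) made up the remaining 7 of the 8 largest increases. Of 30 cell cycle genes, 10 rose and 0 fell, and 22 rose when adjusted over the list alone, with Prc1 up by 1.83 ± 0.195 and Kif20a by 1.96 ± 0.239. The list's mean level was 1.36 to 1.43 log2 CPM in the sham libraries and 2.50 to 2.74 in the WT AngII libraries. The camera test called the list with the preset correlation (adjusted p = 8.57e-51) and not with an estimated correlation (adjusted p = 0.0578).

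Matrix genes with a call in the WT mesenteric arteries were few. Col12a1, a fibril-associated collagen, rose by 1.21 ± 0.0984, Ltbp2, a microfibril protein, by 1.44 ± 0.172 and Postn (periostin), a matricellular protein of healing tissue, by 1.17 ± 0.166. Col12a1 was the only collagen called of 21 (13 adjusted over the list alone), Postn the only matricellular gene of 20 (11 adjusted over the list alone) and Ltbp2 the only elastic fibre gene of 19 (4 adjusted over the list alone). The camera tests of the 3 lists gave an adjusted p of 0.303, 0.0578 and 0.303 with an estimated correlation. Values that did not pass the adjustment over all genes included log2 fold changes of 0.87 ± 0.163 for P4ha3, 0.70 ± 0.163 for Plod2, 1.86 ± 0.361 for Acan and 0.94 ± 0.254 for Timp1. No smooth muscle marker of 16 was called (0 adjusted over the list alone), with 0.63 ± 0.204 for Myocd and 0.55 ± 0.275 for Cnn1. No endothelial marker of 12 was called either (0 adjusted over the list alone), with -0.67 ± 0.208 for Cldn5; that list was below the other genes with the preset correlation (adjusted p = 0.000348) and not with an estimated correlation (adjusted p = 0.583).

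In all, 32 genes rose and 0 fell of 17513 tested in the WT mesenteric arteries, and 30 of the 32 rose by at least 2-fold (edgeR adjusted p below 0.05; 1864 genes had an unadjusted p below 0.05 where chance gives 876). Other tools called more, 238 higher and 71 lower with DESeq2 and 197 and 55 with limma voom. With library size alone edgeR called fewer, 15 higher and 0 lower. B and T cell markers stand for lymphocytes, whose source was not tested. They averaged 3.35 log2 CPM in WT AngII replicate 1 against -0.391 to 0.364 in the other 3 WT AngII libraries. Gut and pancreas markers ranged from 0.606 to 9.08 log2 CPM over the 13 libraries, with overlapping ranges in the 3 groups. The count of higher genes fell to 8, 10, 10 and 11 without sham replicates 1 to 4 and to 12, 15, 11 and 19 without WT AngII replicates 1 to 4, and it was 109 without KO replicate 3. With 1 WT library left out, the edgeR adjusted p passed 0.05 for Hmmr (0.0545, sham 4), Ckap2 (up to 0.0644 with AngII 3, sham 1 or sham 2 left out) and Cenpf (up to 0.0632; sham 1, 2 or 3). The same held for Cdk1 (up to 0.12; any but AngII 4), Ccnb1 (up to 0.115; any but sham 2) and Postn (up to 0.0785; any but AngII 2 and sham 4), in edgeR adjusted p.

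**Figure D3:**
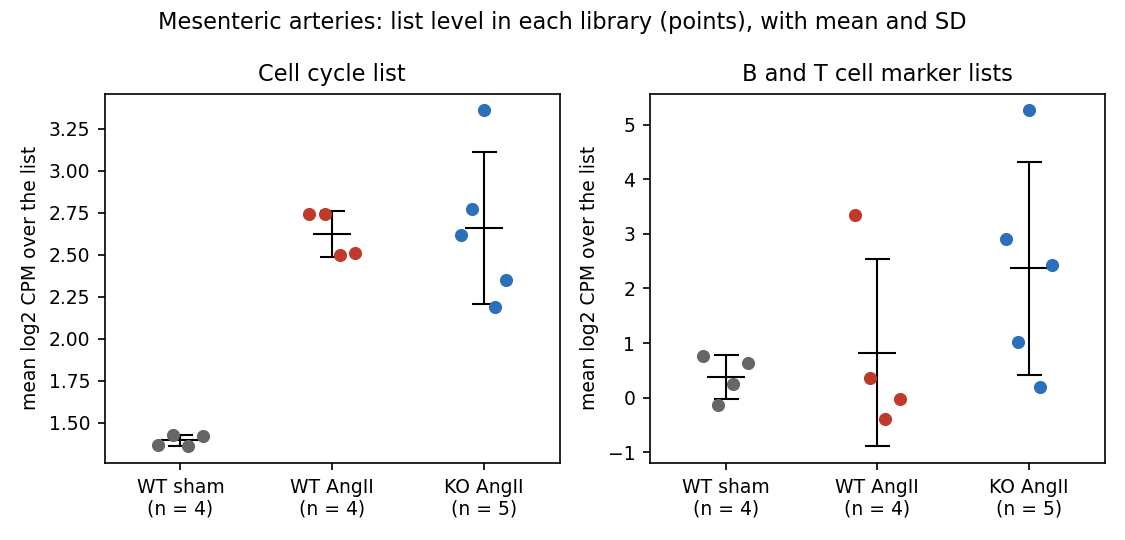
Mean log2 CPM over the cell cycle list (left) and over the B and T cell marker lists (right) in each mesenteric library, by group; points are libraries, and the bars give the mean and SD. All WT AngII and KO AngII libraries (2.19 to 3.36) lie above all sham libraries (1.36 to 1.43) for the cell cycle list, while the B and T cell markers reach 5.26 in KO replicate 3 and 3.35 in WT AngII replicate 1.

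Whether AngII acted differently on the 2 tissues was tested by an interaction over all 26 libraries. The test takes the libraries as independent, and it is not known whether a replicate number marks the same animal in both tissues. Of 18520 genes tested, 434 differed: 308 had a lower and 126 a higher log2 effect in the mesenteric arteries than in the aorta (edgeR adjusted p below 0.05). The genes with the smallest adjusted p among those with a lower effect were Ttc9 (mesenteric minus aortic log2 effect -4.23 ± 0.367), the serine synthesis enzyme gene Psat1 (-1.61 ± 0.186), Cthrc1 (-5.30 ± 0.674), the prion protein gene Prnp (-1.07 ± 0.143) and the engulfment receptor gene Megf10 (-3.66 ± 0.495). Those with a higher effect were led by Scube3 (2.23 ± 0.292), a secreted signalling protein, Fryl (0.85 ± 0.132), the netrin receptor gene Unc5c (1.50 ± 0.234), Ypel2 (0.83 ± 0.131) and AI838599 (1.83 ± 0.291). Each of these 5 fell in the aorta, with mesenteric values of 0.90, -0.03, 0.23, 0.34 and -0.12 that were not called. The matrix genes Col11a1, Col8a1, Thbs1, Col1a1, P4ha3, Lox and Sparc also differed, with differences from -8.17 to -1.10. The AngII effect on Sphk1 was itself lower in the mesenteric arteries (difference -1.33 ± 0.351, edgeR adjusted p = 0.044). This call lies close to the threshold, and whether it holds under the alternatives was not examined.

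Genes called in the mesenteric arteries were nearly all called in the aorta too. Of the 32 that rose there, 31 also rose in the aorta, where 4.81 would be shared by independent lists among the 16089 genes tested in both tissues. Of 4190 genes called in the aorta and tested in both, 3202 (76.4%) had the same sign in the mesenteric arteries. Over all 16089 genes the share with the same sign was 64.2%. The genes that rose in the aorta had a median log2 fold change of 0.741 there and 0.177 in the mesenteric arteries, and those that fell had medians of -0.503 and -0.123. Across genes, which are not independent replicates, the effects in the 2 tissues had a Pearson r of 0.428. Leaving out the aortic and the mesenteric library of 1 number at a time moved the count of lower effects to between 118 (without sham replicate 4) and 448 (without KO replicate 3), and that of higher effects to between 36 (without sham replicate 1) and 233 (without KO replicate 3). Limma voom gave 718 and 542.

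**Figure D4:**
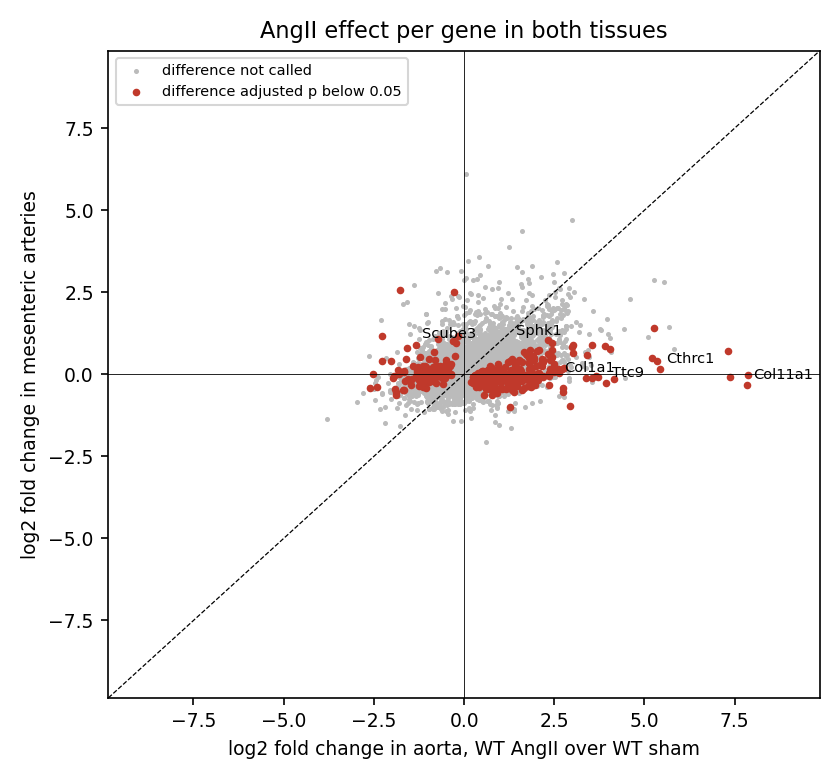
AngII effect per gene in the aorta (horizontal axis) and mesenteric arteries (vertical axis), as log2 fold changes of WT AngII over WT sham; each point is a gene tested in both tissues, red where the effects differ between tissues (edgeR adjusted p below 0.05), and the dashed line marks equal effects. Red points on the right, such as Col11a1 and Cthrc1, lie near 0 on the vertical axis.

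The effect of the smooth muscle deletion under infusion was measured by comparing KO AngII with WT AngII vessels. In the aorta, Sphk1 was the only gene of 16863 with a call. It fell by 2.90 ± 0.262 on the log2 scale (edgeR adjusted p = 0.00046), and the next smallest adjusted p was 0.859. The remaining genes of sphingosine-1-phosphate handling had no call (1 of 14 lower, Sphk1, also when adjusted over the list alone), and the list had a median of 0.0331, a mean of -0.17 and a camera adjusted p of 0.124. No gene of ceramide and sphingomyelin metabolism was called (0 of 25, and 0 adjusted over the list alone), with log2 fold changes of 0.38 ± 0.126 for the ceramide synthase gene Cers6 and -0.32 ± 0.123 for the desaturase gene Degs1. The groups that AngII had raised stayed without a call: 0 of 21 collagen genes, 0 of 20 matricellular genes and 0 of 30 cell cycle genes differed (0 in each adjusted over the list alone), with medians of -0.0991, -0.108 and 8.49e-05. Values of single genes, of these and other lists, included -0.27 ± 0.159 for the collagen gene Col15a1, -0.33 ± 0.141 for the elastic fibre gene Loxl2, -0.36 ± 0.124 for Enpep of the renin-angiotensin list and -0.22 ± 0.083 for the growth factor receptor gene Pdgfrb, with an edgeR adjusted p of 0.981 each.

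Some lists leaned one way in KO aortas without a called member. Of 25 immediate early and stress genes, 23 had negative log2 fold changes, with -1.82 ± 0.572 for the nuclear receptor gene Nr4a1 and -0.76 ± 0.194 for the flow-responsive factor gene Klf2 (edgeR adjusted p = 0.981 each; 0 called, 1 lower adjusted over the list alone). The list median was -0.495. Ccn1, a YAP target, had -1.26 ± 0.424. The 15 adipocyte markers all had positive values (median 0.567; 0 called, 0 adjusted over the list alone), with 1.16 ± 0.65 for Elovl3 and 0.80 ± 0.551 for Cidea. So did 23 of 25 genes of fatty acid oxidation and lipid synthesis (0 called, 0 adjusted over the list alone), with 0.54 ± 0.189 for Me1. Mean adipocyte marker levels were 5.37 to 6.55 log2 CPM in the 5 KO aortas and 5.55 to 6.36 in 3 WT AngII aortas, and 3.90 in WT AngII replicate 4. The 3 lists were called with camera's preset correlation (adjusted p = 3.74e-11, 1.75e-06 and 9.61e-12) and not with an estimated correlation (adjusted p = 0.598, 0.709 and 0.598). Camera called 7 lists up and 3 down in this comparison at the preset correlation, and 0 with an estimated one. Another of them was the neutrophil list (4 of 4 markers positive, median 1.31, 0 called, 2 higher adjusted over the list alone). Its camera adjusted p was 0.000477, and 0.598 with an estimated correlation. Variable single genes included Il6 (3.34 ± 1.10), Mmp13 (2.23 ± 0.796) and the neutrophil gene S100a9 (2.41 ± 0.75). Less variable ones were Adamts8 (0.93 ± 0.222), C7 (0.50 ± 0.147), Csf1r (0.21 ± 0.0799), Calcrl (0.24 ± 0.131) and Cnn1 (-0.35 ± 0.225), all with an edgeR adjusted p of 0.981.

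In all, edgeR called 0 genes higher and 1 lower in KO aortas, with 608 genes at an unadjusted p below 0.05 where chance gives 843. DESeq2 called 4 higher (Adamts8, Dglucy, Hs6st2 and the uncertain Olfr224) and 2 lower (Sphk1 among them), and limma voom called 0 and 1. For 83.0% of genes the 95% interval lay within a 2-fold change either way. On simulated counts with the same spread, the test recovered 92.5% of genes changed 2-fold and 70.1% of those changed 1.5-fold in this comparison. There, 200 genes changed at once, all with an average log2 CPM of at least 1, and genes varied independently. The adjustment is stricter where fewer genes change. These shares therefore do not hold for genes of lower expression or for a few changed genes. Without KO replicate 5 a further gene was called, Chad, with a log2 fold change of -1.72 (edgeR adjusted p = 0.047).

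In the mesenteric arteries, Sphk1 was again the only gene called between KO and WT AngII mice, lower by a log2 fold change of -1.83 ± 0.195 (edgeR adjusted p = 0.0101). Lymphocyte markers had positive values in KO vessels without a call. These were all 9 B and plasma cell markers (median 1.95) and all 13 T and NK cell markers (median 1.57), with 2.63 ± 1.34 for Jchain and 1.86 ± 0.951 for Ighm, both parts of immunoglobulin M (0 called in each list, 0 adjusted over the list alone). Their mean level was 5.26, 2.91, 2.43, 1.03 and 0.2 log2 CPM in KO replicates 3, 1, 5, 2 and 4, against 3.35, 0.364, -0.0276 and -0.391 in WT AngII replicates 1, 2, 4 and 3. Among genes of lymphoid homing, log2 fold changes of 2.93 ± 1.22 for Madcam1 and 1.85 ± 0.609 for Cxcl13 were not called (edgeR adjusted p = 0.798). Both lymphocyte lists were called with camera's preset correlation (adjusted p = 5.18e-05 and 1.15e-05) and not with an estimated correlation (adjusted p = 0.589 each).

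Some lists had mostly negative values in KO mesenteric arteries, and others of the vessel wall did not, such as the fibroblast markers (8 of 12 positive, median 0.0426). Of 19 Notch and arterial identity genes 18 had negative values (median -0.239), with -0.51 ± 0.202 for Heyl, and 18 of 21 collagen genes did so (median -0.12). Ion channel genes had a median of -0.14, with -0.51 ± 0.198 for the potassium channel gene Kcna5, and vasoactive signalling genes one of -0.0905, with -0.32 ± 0.132 for Gucy1a1. No member of these 4 lists was called, over all genes or adjusted over the list alone (0 in each), and camera's calls of them with the preset correlation did not hold with an estimated correlation (adjusted p = 0.556, 0.67, 0.609 and 0.556). Further values, each with an edgeR adjusted p of 0.798, were -0.58 ± 0.155 for the sphingomyelin synthase gene Sgms2, -2.54 ± 0.857 for Spp1, -3.01 ± 0.868 for the neutrophil gene Ltf, -0.52 ± 0.171 for Egr1, -0.39 ± 0.124 for Fgf2, -0.40 ± 0.12 for Skil and -0.38 ± 0.118 for Crim1. On the positive side stood 0.70 ± 0.166 for Cdkn1a, 0.62 ± 0.164 for Sesn2, 0.62 ± 0.264 for Tnc and 0.38 ± 0.16 for Ltbp2, each also at an edgeR adjusted p of 0.798.

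In all, edgeR called 0 genes higher and 1 lower in KO mesenteric arteries, with 872 genes at an unadjusted p below 0.05 where chance gives 876. DESeq2 called 1 higher (Kcnj15) and 1 lower (Sphk1), and limma voom called 0 and 0. For 76.1% of genes the 95% interval lay within a 2-fold change either way. On simulated counts the test recovered 71.6% of genes changed 2-fold in this comparison, with the limits given for the aorta. The call of Sphk1 was lost without WT AngII replicate 1, WT AngII replicate 3 or KO replicate 5 (log2 fold changes -1.81, -1.84 and -1.81) and with limma voom (-1.79, adjusted p = 0.0545). It was also lost with library size alone (edgeR adjusted p = 0.0563) and in a fit of only the 2 groups (edgeR adjusted p = 0.262). Among alternatives chosen after seeing the data, it was lost without KO replicate 3 and WT AngII replicate 1 together (edgeR adjusted p = 0.0571) and with lymphoid and gut or pancreas covariates (edgeR adjusted p = 0.196). Cdkn1a was called without KO replicate 3 (0.84, edgeR adjusted p = 0.0243). Without the 4 libraries with over 10% of records not aligned, an alternative chosen after seeing the data, 56 genes were called higher, Cdkn1a (0.93) and Madcam1 (4.57) among them (edgeR adjusted p = 0.0298 each). No gene had a KO effect that differed between tissues (0 of 18520 with edgeR, 749 at an unadjusted p below 0.05, 0 with limma voom).

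The remaining comparison, KO AngII against WT sham, changes genotype and infusion together and is given as counts. In the aorta 2796 genes were higher and 2401 lower, or 2192 and 4075 when scaled by library size alone, which put the median log2 fold change at -0.105. In the mesenteric arteries 80 genes were higher and 44 lower, or 898 and 507 with DESeq2, 266 and 213 with limma voom, 65 and 70 with library size alone, and 15 and 0 in a fit of only the 2 groups. Sphk1 was lower than sham in both tissues, with log2 fold changes of -0.88 ± 0.266 in the aorta (edgeR adjusted p = 0.022) and -1.13 ± 0.194 in the mesenteric arteries (edgeR adjusted p = 0.0227). The aortic call was lost without KO replicate 2, sham replicate 2 or sham replicate 3 (log2 fold changes -0.79, -0.84 and -0.73). The mesenteric call was lost without KO replicate 1 or any sham replicate from 1 to 4 (-1.04, -1.08, -1.19, -1.08 and -1.16). It was also lost in a fit of only the 2 groups (edgeR adjusted p = 0.0645) and with lymphoid and gut or pancreas covariates, chosen after seeing the data (edgeR adjusted p = 0.0852). The mesenteric counts fell to 22 higher without sham replicate 4 and to 0 lower without sham replicate 2.

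The deletion was also asked to oppose the AngII effect gene by gene. Of the 4301 genes that AngII changed in the WT aorta, 2194 (51.0%) had a KO effect of the opposite sign, and the median KO effect was 0.00133 for the genes that rose and 0.00609 for those that fell. Simulations with an AngII effect and no KO effect, in which the comparisons also share the WT AngII libraries, gave a mean of 57.4% (55.4% to 59.3%) and mean medians of -0.023 and 0.0338. Only Sphk1 was called in opposite directions in the 2 comparisons (1 gene in the aorta against 0.147 for independent lists, and 0 against 0.00183 in the mesenteric arteries). Across genes, which are not independent replicates, the 2 sets of log2 fold changes had an r of -0.0156 in the aorta and -0.0585 in the mesenteric arteries, whereas unchanged groups sharing the WT AngII libraries gave mean values of -0.527 and -0.532 in 20 simulations. With the AngII effect and no KO effect simulated, the mean r was -0.218 and -0.525. The covariance was -0.00233 in the aorta against -0.0328 simulated, and -0.0089 in the mesenteric arteries against -0.0918, differences of 0.0305 and 0.0829. With the WT AngII libraries split so that no library entered both comparisons, the mean r over 6 splits was 0.174 (-0.0549 to 0.378) in the aorta and 0.318 (-0.0916 to 0.503) in the mesenteric arteries. All the simulations drew each gene independently, with the same spread in every group. Their ranges leave out genes that vary together, and so understate how far such values can vary by chance.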

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

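The 3 tests of the first pattern weighed below and the first test of the second were chosen after the result was seen; the others were written down before.

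The first pattern is that AngII changed far more genes in the aorta than in the mesenteric arteries. A larger spread between mesenteric libraries with effects of the same size was tested on genes chosen in 1 set of aortic libraries. These were the 500 genes with a rise and the smallest edgeR p. Their mesenteric median log2 fold change was 0.265 of the median in the held-out aortic libraries (0.218 to 0.407 over 36 choices). This argues against effects of the same size on such genes. Choosing genes by their aortic rise can favour the aorta, and none were chosen in mesenteric libraries. For other genes, a larger spread as a reason for the lower count stays open. Smooth muscle markers stood at 0.972 of the aortic sham level at the median, but from 0.181 to 104 times for single markers (15 of 16 at 0.5 or more). The level in undiluted mesenteric arteries was not measured, so dilution of vessel RNA stays open. With lymphoid and gut or pancreas marker levels as covariates 42 genes were called, which argues against varying amounts of such tissue as the whole cause. Whether mesenteric arteries respond less at 14 days therefore stays open too, since dilution could lower their log2 effects.

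The second pattern is that matrix genes rose in the aorta while 4 of 16 smooth muscle markers fell. The smooth muscle list was not called with an estimated correlation (adjusted p = 0.531), and its mean differed by -0.37 (exact permutation p = 0.114). A lower share of smooth muscle RNA would raise the other cell types alike. Macrophage markers moved 0.729 log2 units more than endothelial ones (SD 0.20 in sham and 0.16 in AngII libraries; exact permutation p = 0.0286, n = 4 each), which argues against a lower share as the only change. All 12 fibroblast markers moved 0.527 more, but the 7 that encode no matrix protein only 0.0163 more. Endothelial markers themselves differed by 0.044 (SD 0.15 in sham and 0.21 in AngII libraries), below the collagen median of 1.38 by more than their spread, which argues against a lower share as the cause of the matrix rise. With the adipocyte marker level as a covariate, 20 collagen genes were still called higher and 8 smooth muscle markers lower. This argues against adipose tissue as the cause. With library size alone the counts were 19 and 9. For the collagen genes, this argues against a few abundant genes as the cause. For the smooth muscle markers it decides nothing, since that scaling also put the median log2 fold change of all genes at -0.126. More matrix transcripts per cell, or a changed mix of cells, may each account for the pattern, and whole vessels cannot separate them.

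The third pattern is that 10 of 30 cell cycle genes rose in the mesenteric arteries, in a list not called with an estimated correlation (adjusted p = 0.0578). Without KO replicate 3 and WT AngII replicate 1, the 2 libraries richest in lymphocyte markers, the list's median was 1.39. Of these 2, only WT AngII replicate 1 belongs to the groups compared here. With lymphoid and gut or pancreas covariates the median was also 1.39, against 1.43 in all libraries. These values argue against dividing lymphocytes or epithelial cells as the whole cause. Division of vessel wall cells or of infiltrating macrophages stays open and untested, as a hypothesis.

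Effects of AngII that differed between the tissues number 434 genes (edgeR interaction test). Beside those of the report (Ttc9 -4.23, Psat1 -1.61, Cthrc1 -5.30, Prnp -1.07, Megf10 -3.66, Scube3 2.23, Fryl 0.85, Unc5c 1.50, Ypel2 0.83, AI838599 1.83 and Sphk1 -1.33, as mesenteric minus aortic log2 effects), lower mesenteric than aortic effects were found for Col11a1 (-8.17), Tnmd (-4.96), Ddah1 (-4.30), Col8a1 (-3.29), P4ha3 (-3.07), Fst (-2.60), Ccr2 (-2.38), Thbs1 (-2.14), Col1a1 (-1.92) and Comp (-1.91). The same direction held for Lum (-1.77), Dpt (-1.64), Timp1 (-1.50), Sparc (-1.34), Col5a2 (-1.31), Lox (-1.10), Tpm4 (-0.92), Cdkn1a (-0.87), Ace (-0.84) and Piezo1 (-0.75). Noxo1 (1.38), Gucy1a1 (0.98) and Gucy1b1 (0.88), which fell in the aorta, had differences of the other sign.

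Single libraries far from the rest of their group were found in 20 of 468 groups tested, where chance marks about 1 in 20 groups and so 23.4. In the aorta, in log2 CPM with Dixon's ratio in brackets, they were Tnmd (6.28 in KO 5; 0.799), Ttc9 (3.15 in KO 5; 0.717), Atcayos (0.777 in KO 1; 0.733), Dpt (8.77 in KO 3; 0.758), Ccl21a (2.79 in KO 3; 0.714), Pdgfrb (8.94 in KO 4; 0.791), Spns2 (3.86 in WT AngII 4; 0.96), Sox17 (3.33 in WT AngII 4; 0.912), Ncf1 (3.14 in sham 1; 0.884) and Cdkn1a (5.03 in sham 4; 0.848). Aortic sham 1 also had the most gene counts of its group (32.2 M; 0.957), and the few gut and pancreas markers tested in the aorta were highest in WT AngII 1 (1.59; 0.833) and KO 3 (1.64; 0.75). In the mesenteric arteries they were Ckap2 (-1.13 in sham 3; 0.851), P4ha3 (2.58 in sham 2; 0.951, and 2.89 in KO 3; 0.738), Acan (0.0243 in KO 3; 0.728), Cdkn1a (6.05 in KO 3; 0.812), Madcam1 (1.65 in WT AngII 1; 0.912) and the endothelial marker mean (6.80 in KO 4; 0.75).

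Records that did not align, which no comparison uses, made up 11.43%, 14.7% and 14.23% of mesenteric KO replicates 2, 3 and 4 and 12.02% of mesenteric WT AngII replicate 1, against at most 2.52% in the mesenteric sham libraries. The reads themselves were not analysed here, so their origin is not known.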

How the results depend on the processing

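Leaving out KO AngII 3 with WT AngII 1, leaving out the 4 libraries rich in unaligned records, and the lymphoid and gut or pancreas covariates were chosen after seeing the data. In the aorta the direction and call of Sphk1 held under every alternative for AngII and for KO AngII against WT AngII. RLE factors, the stricter filter and the adipocyte covariate changed no count of called genes over all genes by over 1.5 times. Of 16 smooth muscle markers in the aorta, 8 fell with the adipocyte covariate and 9 with library size alone, against 4. The values below moved further, and the cause was not tested.

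With an estimated correlation between genes, the lists called up and down numbered 8 and 0 for AngII in the aorta (20 and 5 with the preset one), and 0 and 0 for KO in the aorta (7 and 3), AngII in the mesenteric arteries (14 and 4) and KO there (12 and 8). DESeq2 called 4 higher and 2 lower for KO in the aorta, and in the mesenteric arteries 238 and 71 for AngII, 1 higher for KO and 898 and 507 for KO AngII against WT sham. Limma voom called there 197 and 55 for AngII, 0 lower for KO (Sphk1 -1.79, adjusted p = 0.0545) and 266 and 213 for KO AngII against WT sham, and 542 and 718 genes with a mesenteric AngII effect above and below the aortic one. Library size alone gave 3729 lower for AngII and 4075 lower for KO AngII against WT sham in the aorta, and in the mesenteric arteries 15 higher for AngII, 0 lower for KO (Sphk1 -1.81, adjusted p = 0.0563) and 70 lower for KO AngII against WT sham. With no filter, 27 genes were lower for mesenteric KO AngII against WT sham, and 63 had a mesenteric effect above the aortic one. Fits of only the 2 groups compared gave in the mesenteric arteries 72 higher and 6 lower for AngII, 0 lower for KO (Sphk1 -1.82, adjusted p = 0.262) and 15 and 0 for KO AngII against WT sham (Sphk1 -1.11, adjusted p = 0.0645; all by edgeR).

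Without KO AngII 3 and WT AngII 1 together, the mesenteric counts were 1 lower for AngII, 0 lower for KO (Sphk1 -1.90, adjusted p = 0.0571) and 124 higher for KO AngII against WT sham. Without the 4 libraries rich in unaligned records they were 2 lower for AngII, 56 higher for KO with 2 lists down, and 270 and 19 for KO AngII against WT sham. With the lymphoid and gut or pancreas covariates they were 2 lower for AngII, 0 lower for KO (Sphk1 -1.89, adjusted p = 0.196) with 7 lists up, and 22 and 0 for KO AngII against WT sham (Sphk1 -1.23, adjusted p = 0.0852). At an adjusted p below 0.1, 60 genes rose in both tissues (12.7 for independent lists). With the WT AngII libraries split, the opposition of AngII and KO effects reversed in sign, with r of 0.174 and covariance of 0.0428 in the aorta and 0.318 and 0.0909 in the mesenteric arteries; the shared libraries make the unsplit values negative by construction.

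The replicate numbers did not pass the check set in advance, which asked for every correlation above 0.1. Weakly paired libraries can fail this check too, so it does not show that the numbers are unrelated to pairing. Whether a number marks 1 animal in both tissues is not known. The correlation of deviations between libraries with the same number was -0.289 to 0.102 in the aorta (1 of 12 above 0.1) and -0.265 to 0.343 in the mesenteric arteries (7 of 12), and across tissues -0.129 to 0.198 (4 of 13; 6 of 13 matched best with their own number). As a replicate block the number gave 1 higher and 2 lower for KO and Sphk1 at -0.92 (adjusted p = 0.0598) for KO AngII against WT sham in the aorta. In the mesenteric arteries it gave 8 higher for AngII, 0 lower for KO (Sphk1 -1.81, adjusted p = 0.267), and 19 and 1 for KO AngII against WT sham (Sphk1 -1.14, adjusted p = 0.0923). As a block across tissues, it gave 52 and 138 genes with a mesenteric AngII effect above and below the aortic one. It also ended the calls of Ccl21a in the aorta (adjusted p = 0.0567) and of Ccnb1 (0.0505), Kif20a (0.0724), Ckap2, Ltbp2 and Postn (0.086 each) and Cenpf (0.0937) in the mesenteric arteries.

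With 1 library left out at a time, the aortic counts ranged over 1943 to 2634 higher and 1288 to 2062 lower for AngII (Sphk1 1.86 to 2.19), 0 to 0 and 1 to 2 for KO (Sphk1 -3.07 to -2.75), and 2252 to 3057 and 1907 to 2849 for KO AngII against WT sham (Sphk1 -1.04 to -0.73). The mesenteric counts ranged over 8 to 109 and 0 to 7 for AngII (Sphk1 0.55 to 0.85), 0 to 1 and 0 to 1 for KO (Sphk1 -1.96 to -1.68), and 22 to 120 and 0 to 45 for KO AngII against WT sham (Sphk1 -1.22 to -1.04). Genes with a mesenteric AngII effect above and below the aortic one numbered 36 to 233 and 118 to 448 (without sham 1, 36 and 158; sham 3, 38 and 158; sham 4, 43 and 118; WT AngII 1, 47 and 135; WT AngII 3, 64 and 205; WT AngII 4, 205 above), and those with a different KO effect 0 to 0. Of the values of named genes other than Sphk1 under all alternatives, 3022 kept their direction and side of the threshold, 25 passed it, such as P4ha3, Plod2, Sqle and Acan in the mesenteric arteries with DESeq2, 36 lost it and none reversed. The dispersions were 0.127 in the mesenteric arteries and 0.0286 in the aorta. At these depths, simulated 2-fold AngII changes were recovered for 62.7% and 83.6% of the changed genes, in that order. The changed genes all had an average log2 CPM of at least 1.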

Other observations

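The alternatives that leave out mesenteric libraries or add marker covariates were chosen after seeing the data; the splits of the libraries were planned.

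Further genes changed in the WT aorta after AngII. Cdkn1a, the cell cycle inhibitor p21, rose by 1.32 ± 0.0932, from 40.1 ± 5.06 to 100 ± 6.84 CPM (n = 4 each; edgeR adjusted p = 2.08e-06), beside the rise of the cell division genes. Of 22 SRF and YAP target genes, 7 rose and 1 fell (8 and 3 adjusted over the list alone), with Tpm4, a tropomyosin, up by 1.13 ± 0.096 and Ccn2, a matricellular growth factor, by 1.46 ± 0.271; the list was not called (camera adjusted p = 0.109, and adjusted p = 0.824 with an estimated correlation). Sox17, an endothelial transcription factor, fell by 0.61 ± 0.137 and Hey2, a Notch target, by 0.58 ± 0.126, among 4 of 19 Notch and arterial identity genes that fell (4 adjusted over the list alone; list not called, camera adjusted p = 0.0913, and adjusted p = 0.417 with an estimated correlation). The clock genes Nr1d1 and Per2 fell by 0.63 ± 0.132 and 0.59 ± 0.154, in a list with 4 lower and 1 higher of 18 (6 and 3 adjusted over the list alone; list not called, camera adjusted p = 0.202, and adjusted p = 0.422 with an estimated correlation); the hour of collection is not given in the labels.

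Some lymphatic and immune genes changed as well. Of 7 lymphatic endothelial markers 6 rose (6 adjusted over the list alone), with the chemokine gene Ccl21a up by 2.49 ± 0.606 and the growth factor receptor gene Flt4 by 0.96 ± 0.246 (adjusted p = 0.345 for the list with an estimated correlation). Ciita, the regulator of class II antigen presentation, rose by 1.73 ± 0.415, among 5 of 15 antigen presentation genes (8 adjusted over the list alone; adjusted p = 0.587 with an estimated correlation), and Vcam1, a leukocyte adhesion molecule, by 0.85 ± 0.141, among 7 of 10 adhesion genes with 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.0728 with an estimated correlation). Red cell markers were lower, 4 of 5 (5 adjusted over the list alone; adjusted p = 0.389 with an estimated correlation). All 30 oxidative phosphorylation genes had negative values, with a median of -0.194 and 2 called (0 adjusted over the list alone; adjusted p = 0.723 with an estimated correlation).

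In the WT mesenteric arteries, 18 of 19 cholesterol synthesis genes had positive values after AngII, among them 0.80 ± 0.163 for the squalene epoxidase gene Sqle (edgeR adjusted p = 0.0881). None was called over all genes (0 of 19), 14 were higher adjusted over the list alone, and the list passed fry (adjusted p = 0.0486) and camera's preset correlation (adjusted p = 8.81e-16), with adjusted p = 0.157 with an estimated correlation. Cers6, a ceramide synthase gene, had 0.74 ± 0.169, Ccn2 0.86 ± 0.242 and Notch3 -0.58 ± 0.201 (edgeR adjusted p = 0.137, 0.221 and 0.335). The 12 macrophage markers were all positive with no call (0 of 12, and 0 adjusted over the list alone; median 0.855; adjusted p = 0.641 with an estimated correlation).

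The 56 genes called higher in KO mesenteric arteries without the 4 libraries rich in unaligned records included lymphocyte genes such as Cd4 (3.85), Ms4a1 (2.89) and Pax5 (3.01), the macrophage genes Marco (6.58) and Spic (3.63), and Glycam1 (8.23), a mucin of lymph node venules, in log2 fold changes; these genes were chosen after their values were seen. KO replicates 1 and 5, which remain in that fit, had lymphocyte marker means of 2.91 and 2.43 log2 CPM against at most 0.364 in the WT AngII libraries that remain. The 56 genes could therefore reflect lymphoid tissue in the dissection or lymphocytes in the vessel wall, and no test here separates these.

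Other splits of the same libraries were fitted to see how often chance gives as many calls. For the AngII effect, only the real split gave as many in each tissue, 1 of 35. It called 4301 genes in the aorta (highest other 38) and 32 in the mesenteric arteries (highest other 0). That is the smallest share that the splits allow, and it lies under the limit set in advance for excluding chance. The same holds for KO AngII against WT sham, with 1 of 100 in the aorta (5197; highest other 1400) and 1 of 100 in the mesenteric arteries (124; highest other 1). For the KO effect, 7 of 100 splits in the aorta called at least 1 gene (highest other 57), so chance cannot be excluded for the count. In the mesenteric arteries 4 of 100 did so (highest other 447), and for the tissue difference of the AngII effect 3 of 100 splits gave 434 genes or more (highest other 1140). Both shares lie under the limit that was set in advance for excluding chance. For the mesenteric KO effect the real count is 1 gene and another split called 447, so its share decides little. In the splits for the tissue difference, each tissue was regrouped apart. A split that keeps the real aortic groups then still holds the aortic AngII effect, so the 3 of 100 do not measure chance. For the tissue difference of the KO effect the real count is 0, which all 100 splits reach by construction (highest other 0), so this count decides nothing. Which libraries the splits with 57, 447, 1140 and 1400 genes bring together was not examined, so their cause is not known.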
